A study of Homo sapiens with 24 samples.

How the data were processed

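The data are peak lists from CUT&RUN, an assay in which an antibody brings a nuclease to chromatin and the DNA fragments released around the bound protein are sequenced. All 24 libraries came from HUDEP-2, an established human erythroid progenitor line, in 3 edited clones. Clone T carries the nuclear receptor TR4 (gene NR2C2) with FLAG and MYC epitopes, clone B carries the repressor BCL11A with HA and MYC epitopes, and clone TB carries both. Antibodies against MYC, HA or TR4 gave 7 groups of 3 libraries, and IgG gave 1 library per clone. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

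Per the submitters' processing notes, Trimmomatic, Bowtie2, Picard, SAMtools and MACS2 2.1.4 were used and the genome build was GRCh38; the role of each tool is not given in the sources used here. The authors deposited 1 peak list per library, so peaks were called library by library. Each deposited peak has a fold enrichment (a linear ratio) and a −log10 q-value as the authors' peak caller gave them. The other value used from each deposited list was the summit's offset from the peak start. The lowest −log10 q in a target library's list ranged from 2.00 to 2.05. The folds are the authors' own values and were used only to describe or rank peaks within a list, so folds of different lists were not tested against each other. Read counts were not analysed here, so sequencing depth is unknown and list length is the only value that stands near it. Lists of the 21 target libraries held 4621 to 31432 peaks, and those of the 3 IgG libraries 2036 to 4828. No confidence interval that needs depth is given.

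Peaks of all 24 libraries were merged where they shared at least 1 base, which gave 79570 regions with a median width of 111 bases. The 7349 regions with an IgG peak were left out of comparisons. A group region had a peak in at least 2 of the 3 libraries. Overlaps of group regions were set against the number expected from independence with Fisher's exact test (two-sided) over the 72221 regions left. Of these, 35078 had a peak in only 1 target library and so could not be group regions. They lower the number expected and raise the odds ratio. Regions are not replicates, so the Jaccard index between libraries (shared regions over regions in either) was given beside each overlap with an exact permutation test, one-sided, of the 3 against 3 labels, for which the smallest p is 0.1. For the comparison of targets, 9 TR4-directed libraries (MYC and TR4 antibodies in clone T, TR4 antibody in clone TB) were set against 9 BCL11A-directed libraries (MYC and HA antibodies in clone B, HA antibody in clone TB). The MYC libraries of clone TB were left out there because both proteins carry that epitope. Each region with a peak in at least 4 of the 18 libraries was tested with Fisher's exact test (two-sided) on the number of libraries, with Benjamini-Hochberg adjustment at 0.05. Differences in means used exact two-sided permutation tests, and the Jaccard index by target used 100000 permutations.

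Gene positions came from a RefSeq gene table of the same build, which gives the start and end of 20037 protein-coding genes on the primary chromosomes but no strand and no exons. The planned promoter windows around transcription start sites could not be drawn from it, so windows of 1 kb around both ends of each gene record took their place, and named regions carry the gene with the nearest end in place of the nearest start site. These windows also hold the 3′ ends of genes. The globin genes are the exception, since their strands are textbook knowledge, and windows there were set around the 5′ end. Whether a region lies in an exon, intron or UTR is not given. The planned motif comparison was not run, because no genome sequence was used here. For 16 gene lists fixed before the data were examined, members with a group region were compared with all other protein-coding genes by Fisher's exact test (two-sided), and members with a region of one target alone by an exact McNemar test, each Benjamini-Hochberg adjusted over the lists. In all counts of genes, a TR4 region was a MYC region of clone T and a BCL11A region a MYC region of clone B.

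Genes and regions were named by a rule fixed before the data were examined. It takes all globin genes, BCL11A, NR2C2, ZBTB7A and LIN28B. From every other list it takes up to 4 members with a peak at a gene end in the most MYC libraries of clones T and B. It also takes the 8 regions with the highest mean fold percentile in each class of the MYC comparison, and the 8 with the lowest p in each direction of the test by region. Of these the text prints those its comparisons need. A p of 2.23e-308 is an upper bound.

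The test by region was checked on simulated lists of 66750 regions. With the real list lengths and 4000 changed regions, 98.2% were recovered, none in the wrong direction, and 114 unchanged regions were called BCL11A-preferred against 0 called TR4-preferred. With 200 changed regions 59% were recovered. Changed regions were given a peak in nearly all libraries of one target and nearly none of the other. Libraries were drawn independently, with no likeness by clone or antibody, so these rates hold for that setting alone. In the data 67 TR4-preferred and 1007 BCL11A-preferred regions were 9 libraries against 0. No 2 libraries had identical lists, and the highest Jaccard index between any 2 was 0.615. Replicate numbers are shared by the groups, so it was checked whether same-numbered libraries deviated together from their group means. In 1 of 21 pairs of groups, MYC and HA in clone B, all 3 correlations were over 0.1 (0.147, 0.193 and 0.358). MYC and TR4 in clone T had 0.0629, 0.263 and 0.456, so the rule of all 3 can miss a likeness of some replicates. The pairing comes from the replicate numbers in the labels. For that pair the test of peak numbers gave p = 0.5 without and p = 0.25 with the replicate number as a block (exact permutation tests). With 3 libraries against 3 the first test cannot go below 0.1 and the blocked one not below 0.25, so no call could change.

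Alternatives were a stricter −log10 q of at least 5, the 4621 strongest peaks of each library, IgG regions kept, a peak in all 3 libraries, windows of 100 bases on either side of summits, overlap of 50% of the shorter region, gene windows of 500 bases and 5 kb, a replicate block, the MYC libraries left out, and each library left out in turn. Primary chromosomes alone and replicate 3 of every group left out were added after seeing the data, as were the alternatives for the α-globin genes. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.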

Results

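Binding of TR4 and BCL11A was profiled by CUT&RUN in HUDEP-2 erythroid cells to ask how TR4 acts on the γ-globin genes and how its binding compares with that of BCL11A, a known repressor of those genes. The 7 groups of 3 libraries differ in antibody and clone, and 3 IgG libraries give the background. BCL11A lists were longer than TR4 lists on average, without passing the test. With the MYC antibody, clone B gave 24741 ± 9851 peaks (SD, n = 3) and clone T 10696 ± 5288 (SD, n = 3), a ratio of 2.31. Within clone TB the HA antibody gave 22087 ± 6175 peaks and the TR4 antibody 9981 ± 2630 (SD, n = 3 each), a ratio of 2.21. Exact permutation tests gave p = 0.2 and p = 0.1 (two-sided, adjusted p = 0.6 for both over 6 pairs of groups), where 3 libraries against 3 cannot go below 0.1. The third replicate had the shortest list in all 7 groups.

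At the β-globin locus on chromosome 11 (GRCh38), BCL11A-directed libraries had peaks at the globin genes and TR4-directed libraries had nearly none. At the 5′ end of HBB, the adult β-globin gene (5225464 to 5227071), all 9 BCL11A-directed and 0 of 9 TR4-directed libraries had a peak (Fisher's exact test, p = 4.11e-05). The region there, 5226533 to 5227262, was called in the test by region (Fisher's exact test, adjusted p = 0.000938), with a fold enrichment of 9.94 ± 3.44 in the MYC libraries of clone B (SD, n = 3). At HBG1 (5248269 to 5249857) and HBG2 (5253188 to 5254781), the fetal γ-globin genes, 5 of 9 BCL11A-directed and 0 of 9 TR4-directed libraries had a peak (Fisher's exact test, p = 0.0294 for each gene). These regions were not called after adjustment over all regions (Fisher's exact test, adjusted p = 0.0731). HBG1 and HBG2 are near-identical copies, so reads cannot always be assigned to one of them.

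The γ-globin peaks were not found in every library of clone B. Both genes had a peak in 3 of 3 HA and 3 of 3 MYC libraries of clone TB, but in clone B only replicate 1 of the HA and of the MYC antibody had one. At HBG1 these clone B peaks were weak, with folds of 4.77 (HA) and 5.42 (MYC) and −log10 q of 3.84 and 5.14. In clone TB the HBG1 folds were 17.2 to 19.8 with HA (−log10 q 32.4 to 37.6) and 6.10 to 12.1 with MYC (5.74 to 20.3). Folds of different lists were not tested against each other. With the HA antibody, 3 of 3 libraries in clone TB against 1 of 3 in clone B had the HBG1 peak, which did not pass (Fisher's exact test, two-sided, p = 0.4, where 3 libraries against 3 cannot go below 0.1), and the MYC libraries of clone TB can hold TR4 as well as BCL11A. HBE1, the embryonic ε-globin gene, had a peak in 1 HA library of clone TB, and HBD in 3 of the 9 BCL11A-directed libraries. At BGLT3, a noncoding RNA gene between the adult and fetal genes, 7 of 9 BCL11A-directed libraries and 1 of 9 TR4-directed libraries had a peak within 1 kb of the 5′ end, and at the pseudogene HBBP1 5 of 9 and 0 of 9. No IgG library had a peak at any of these 5′ ends. With each list limited to its 4621 strongest peaks, none of these genes passed: HBB had a peak in 2 more BCL11A-directed than TR4-directed libraries (exact p = 0.471), HBG1 and HBG2 in 3 more (exact p = 0.206) and HBBP1 and BGLT3 in 4 more (exact p = 0.0824). HBG1 also missed the threshold at −log10 q of at least 5 (exact p = 0.0824), and within 500 bases BGLT3 had a difference of 0 libraries.

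One region upstream of the globin genes had a peak in every library of both targets. The stretch from 5280584 to 5281046, which begins 10639 bases beyond the 5′ end of HBE1 on the side of the locus control region, the distal enhancer of the cluster, had a peak in 9 of 9 TR4-directed and 9 of 9 BCL11A-directed libraries and in no IgG library. Its fold enrichment was 13.1 ± 5.35 with MYC in clone T and 18.9 ± 14.6 with MYC in clone B (SD, n = 3 each). The neighbouring region from 5275788 to 5276169 had a peak in 5 TR4-directed and 9 BCL11A-directed libraries (Fisher's exact test, adjusted p = 0.146). Farther out, 5284603 to 5284977 had one in 3 against 9 (adjusted p = 0.0328) and 5288107 to 5288409 in 1 against 9 (adjusted p = 0.00394), by Fisher's exact test with Benjamini-Hochberg adjustment. By the rule of at least 2 of 3 libraries, 5275788 to 5276169 was also a TR4-antibody region of clones T and TB. In the same way 5284603 to 5284977 was a MYC region of clone T. Both were regions of every BCL11A-directed group, so by that rule they too were shared.

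**Figure D1:**
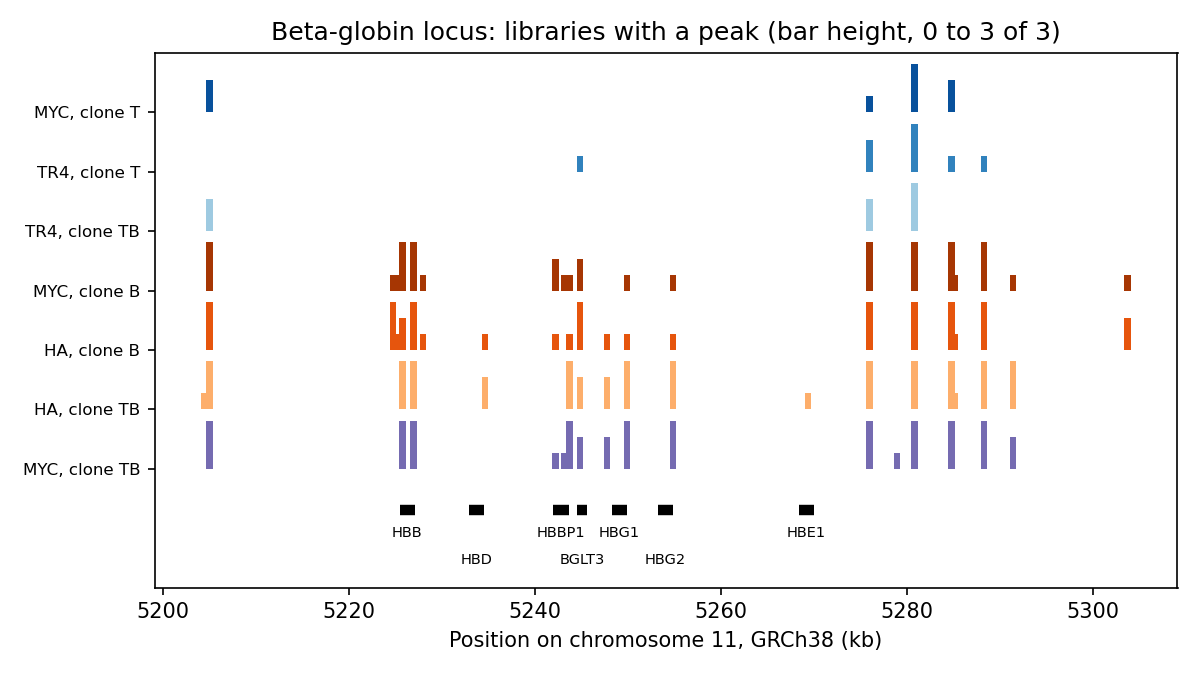
Number of libraries with a peak per merged region (bar height, 0 to 3 of 3 libraries) for the 7 groups, against position on chromosome 11 in kb; black bars are gene records, and the coloured bars are drawn wider than the regions. TR4-directed libraries share the region at 5280584 to 5281046 with all other groups and have no peak at HBG1, HBG2 or HBB.

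The α-globin cluster on chromosome 16 gave a similar contrast. HBZ, the embryonic ζ-globin gene (152644 to 154503), had a peak at its 5′ end in 8 of 9 BCL11A-directed and 0 of 9 TR4-directed libraries (Fisher's exact test, p = 0.000411), and HBA2 (172876 to 173710) in 9 and 1. HBA1 (176680 to 177522) had one in 9 and 5, which did not pass (Fisher's exact test, p = 0.0824). How reads were assigned between HBA1 and HBA2 is not given in the sources used here. HBM had a peak in 8 and 1 libraries, and HBQ1 in 5 and 0. With equal list lengths the difference was 5 libraries for HBZ (exact p = 0.0294), 6 for HBM and for HBA2 (exact p = 0.00905 each), 8 for HBA1, which then passed (exact p = 0.000411), and 0 for HBQ1. HBQ1 also missed the threshold at −log10 q of at least 5 (exact p = 0.0824). Within the gene record of NPRL3, which holds upstream enhancers of the cluster, the regions differed. The region from 138336 to 138886 had a peak in all 18 libraries, and whether it is one of those enhancers was not tested. The region from 113298 to 113853 also had one in 9 and 9, but it had an IgG peak and was left out. Regions from 120009 to 120282 and from 104997 to 105217 had one in 9 and 8 BCL11A-directed and 0 TR4-directed libraries (Fisher's exact test, adjusted p = 0.000938 and 0.00394).

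Across the genome, most TR4 regions were also BCL11A regions when both proteins were profiled through the shared MYC epitope. Of 9608 TR4 regions in clone T, 7458 (77.6%) were among the 21798 BCL11A regions in clone B, where independence predicted 2900 (odds ratio 11.7, Fisher's exact test, p below 2.23e-308, the smallest value the software holds). Regions with a peak in 1 library alone could not be shared and lower the number expected, so part of the excess is built in. Only 34.2% of the BCL11A regions were TR4 regions. The 4 shared regions with the highest mean fold percentile lay within 1 kb of an end of C19orf67, ZHX1-C8orf76, the adaptor gene SHC1 (chromosome 1, 154973589 to 154975103) and the kinase gene PAK4 (chromosome 19, 39125396 to 39126402), each with a peak in all 18 libraries. At SHC1 the fold enrichment was 255 ± 127 with MYC in clone T and 42.2 ± 14.4 with MYC in clone B (SD, n = 3 each). The share fell to 37.1% when every list was limited to its 4621 strongest peaks. The Jaccard index was 0.236 between the groups, against 0.373 and 0.422 within them (exact permutation test, p = 0.1, the smallest possible).

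TR4 regions without a MYC peak in clone B included one in a nuclear receptor gene and one in a ribosomal protein gene. Of the TR4 regions, 1422 (14.8%) had a peak in none of the 3 MYC libraries of clone B. One lay in NR2C1 (chromosome 12, 95072503 to 95073183), which encodes TR2, the partner with which TR4 forms heterodimers. This region had a peak in 9 of 9 TR4-directed and 0 of 9 BCL11A-directed libraries, with a fold enrichment of 105 ± 40.2 with MYC in clone T (SD, n = 3). NR2C1 was not a gene of TR4 alone, since over all regions at its gene ends 9 TR4-directed and 7 BCL11A-directed libraries had a peak. Others lay at CFAP61 and CRNKL1 (chromosome 20, 20052142 to 20052949; fold 242 ± 100, SD, n = 3) and RPL34, a ribosomal protein gene (chromosome 4, 108620267 to 108621049; fold 156 ± 59.2, SD, n = 3), where 1 HA library of clone B also had a peak. Of the BCL11A regions, 11499 (52.8%) had a peak in none of the MYC libraries of clone T. Among the strongest were regions inside GSE1 (chromosome 16, 85381975 to 85382492), where 1 TR4 library of clone TB also had a peak, and near CYB561 (chromosome 17, 63431731 to 63432406) and MGAT3 (chromosome 22, 39452325 to 39453192). Regions of one target alone lay at gene ends less often than shared regions, with 34.1% for TR4 alone, 33.7% for BCL11A alone and 62.9% for shared regions (Fisher's exact test, shared against TR4 alone, odds ratio 3.28, p = 3.66e-84, and against BCL11A alone, odds ratio 3.33, p below 2.23e-308). These classes rest on the MYC libraries of clones T and B. Regions found in all 3 groups of one target with no peak in any library of the other lay at gene ends in 44.5% of 272 cases for TR4 and 27.6% of 3624 for BCL11A.

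The same comparison inside clone TB gave a similar overlap. Of 8459 regions found with the TR4 antibody, 6710 (79.3%) were among the 17956 found with the HA antibody, against 2103 expected (odds ratio 17.9). The share fell to 41.5% with equal list lengths. The Jaccard index was 0.264 between and 0.486 and 0.437 within the groups (exact permutation test, p = 0.1, the smallest possible).

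Antibodies against the same protein found largely the same regions. In clone B, 17296 of 19824 HA regions (87.2%) were MYC regions, and in clone T, 6976 of 8008 TR4-antibody regions (87.1%) were MYC regions. With equal list lengths these shares were 80.5% and 81.4%. Without MYC replicate 1 or 2 of the clone they were 52.8% and 51.8% in clone B and 43.5% and 43.3% in clone T, since both remaining MYC lists, one of them the shortest, then had to hold the peak. Between clones, 6304 of the 8008 TR4 regions of clone T (78.7%) were found in clone TB, and 14472 of the 19824 HA regions of clone B (73.0%), a share that was 48.6% and 48.2% without HA replicate 1 or 2 of clone TB. Of 20429 MYC regions in clone TB, 17132 (83.9%) were MYC regions of clone T or B: 7199 of both, 1342 of clone T alone and 8591 of clone B alone.

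Libraries resembled each other by target. The mean Jaccard index was 0.426 between libraries of one target and 0.246 between targets (permutation test, two-sided, p = 7e-05). Lists of unequal length cannot reach a high index. As BCL11A lists were longer on average, part of this gap, and of the gaps between groups of different targets above, can come from list length. Tested region by region, 6747 of 24485 regions differed between the 9 TR4-directed and 9 BCL11A-directed libraries (Fisher's exact test, Benjamini-Hochberg adjusted), of which 489 were TR4-preferred and 6258 BCL11A-preferred. TR4-preferred regions included single regions near NUDT5 and ALKBH1 and inside the splicing factor gene SRSF6, and BCL11A-preferred ones included regions inside EPAS1, which encodes a hypoxia-inducible factor (chromosome 2, 46339992 to 46340504), inside SLC37A1 and near PTPN18, each in 9 libraries against 0 (Fisher's exact test, adjusted p = 0.000938). When each list was limited to its 4621 strongest peaks, 1598 regions were TR4-preferred and 1486 BCL11A-preferred, or 51.8% TR4-preferred in place of 7.25%. That limit gives both targets the same number of peaks and so by itself brings these counts toward balance. Of the 489 regions, 314 overlapped a TR4-preferred region at equal lengths, as did 783 of the 6258 a BCL11A-preferred one, and 0 changed direction. TR4-preferred regions numbered 795, 785 and 761 without replicate 3 of MYC in clone T, of TR4 in clone T or of TR4 in clone TB, 316 with every region tested, and 112 beside 1545 BCL11A-preferred ones with the MYC libraries left out.

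**Figure D2:**
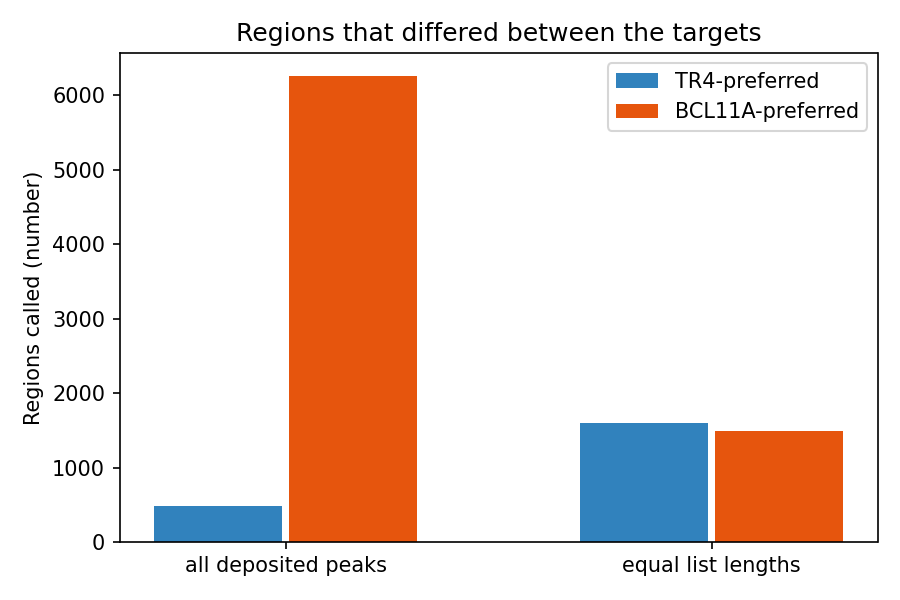
Number of regions called TR4-preferred (blue) and BCL11A-preferred (orange) in the test of 9 against 9 libraries, with all deposited peaks and with equal list lengths. The counts are 489 and 6258 with all peaks and 1598 and 1486 with equal lengths.

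TR4 peaks lay at gene ends more often than BCL11A peaks. The share of peaks within 1 kb of either end of a protein-coding gene was 56.4% ± 3.74 in TR4-directed and 41.6% ± 1.98 in BCL11A-directed libraries (SD, n = 9 each), a difference of 14.9 percentage points (exact permutation test, p = 4.11e-05, the smallest possible). Within clone TB it was 58.6% ± 1.26 with the TR4 antibody and 40.0% ± 0.518 with HA (SD, n = 3 each; exact permutation test, p = 0.1, the smallest possible). In the IgG libraries the share was 2.63% to 4.44%. With equal list lengths the difference was 9.81 percentage points.

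**Figure D3:**
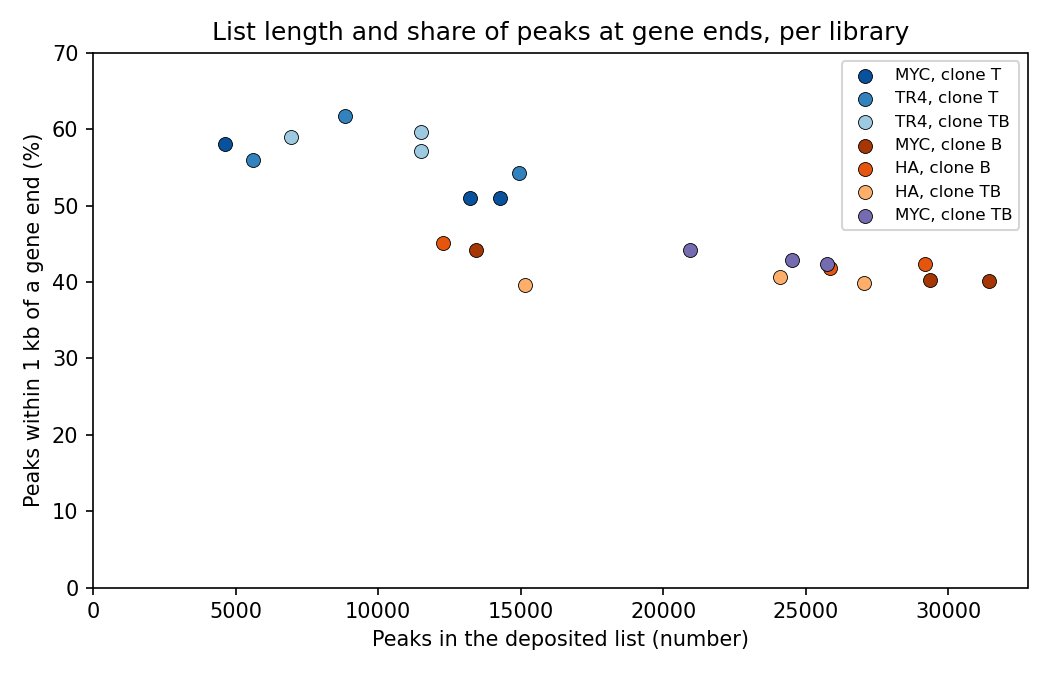
Share of peaks within 1 kb of a protein-coding gene end (%) against the number of peaks in the list, 1 point per target library, coloured by group. TR4-directed libraries lie between 51.0% and 61.7%, and BCL11A-directed libraries between 39.6% and 45.1%.

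Regulators of the fetal globin genes carried regions of both proteins. Here and for the lists below, regions are those of the MYC antibody in clones T and B. Numbers of libraries cover all TR4-directed and BCL11A-directed ones. Among 22 such genes, 15 had a TR4 region at a gene end and 19 a BCL11A region (adjusted p = 0.000207 and 0.00024 against other protein-coding genes, Fisher's exact test), where 5406 and 8903 of the 20037 protein-coding genes had one. Gene activity was not measured, and the other genes were not limited to genes active in these cells. An excess in this or any list below thus cannot be told apart from one at active genes in general. NR2C2, which encodes TR4 (chromosome 3, 14947583 to 15049273), had a fold enrichment of 282 ± 107 with MYC in clone T and 32.4 ± 13.1 with MYC in clone B (SD, n = 3 each). ZBTB7A, a repressor of γ-globin (chromosome 19, 4043303 to 4066899), had 16.3 ± 3.62 and 31.3 ± 12.3 (SD, n = 3 each), and both genes had a peak in all 18 libraries. BCL11A itself had a peak in 6 TR4-directed and 9 BCL11A-directed libraries. LIN28B, a fetal-stage RNA-binding protein, had one in 0 and 1.

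Genes of energy metabolism and translation had regions of both proteins more often than other genes. Those others included 378 of 390 olfactory receptor genes with no peak in any of the 18 libraries. Of 74 oxidative phosphorylation genes, 50 had a TR4 and 57 a BCL11A region (adjusted p = 2.85e-12 and 1.03e-07, Fisher's exact test). NDUFA11, a subunit of respiratory complex I, had a fold enrichment of 111 ± 50.2 with MYC in clone T and 51.4 ± 27.4 with MYC in clone B (SD, n = 3 each). Of 83 ribosomal protein genes, 47 had a TR4 and 62 a BCL11A region (Fisher's exact test, adjusted p = 7.3e-08 and 1.32e-07). Of 31 nucleolar genes known as MYC targets, 19 and 24 had one (Fisher's exact test, adjusted p = 0.000207 and 0.000444), among them NOP2 and RRS1. Both counts rest on the MYC antibody, so its binding to the cells' own MYC protein stays open for them. The nucleolar genes lost the BCL11A call with equal list lengths (Fisher's exact test, adjusted p = 0.251) and with a peak needed in all 3 libraries (adjusted p = 0.26).

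Heme and iron genes, erythroid transcription factors, red cell membrane genes and corepressors had BCL11A regions more often than other genes. Of 23 heme and iron genes, 14 had a TR4 and 20 a BCL11A region (Fisher's exact test, adjusted p = 0.00176 and 0.00015). Among them was FECH, which inserts iron into protoporphyrin to form heme. Another was GLRX5, of iron-sulfur cluster assembly. At GLRX5 the fold enrichment was 106 ± 55.3 with MYC in clone T and 23.3 ± 9.03 with MYC in clone B (SD, n = 3 each). Of 20 erythroid transcription factors, 9 had a TR4 and 17 a BCL11A region (Fisher's exact test, adjusted p = 0.106 and 0.000642). KLF1, the erythroid Krüppel-like factor, had a peak in 8 TR4-directed and 9 BCL11A-directed libraries. Of 24 red cell membrane genes, 5 and 18 had one (Fisher's exact test, adjusted p = 0.647 and 0.00524), and of 26 corepressor genes, such as MBD2 and HDAC1, 13 and 22 (adjusted p = 0.0265 and 0.000108). Of 38 nuclear receptors, 8 and 18 had one, without passing (Fisher's exact test, adjusted p = 0.501 and 0.746), although ESRRA, the estrogen-related receptor α gene, had 146 ± 67.4 with MYC in clone T and 19.1 ± 6.27 with MYC in clone B (SD, n = 3 each). Members with a BCL11A region alone outnumbered those with a TR4 region alone among erythroid transcription factors (8 against 0), red cell membrane genes (13 against 0), corepressors (9 against 0), nuclear receptors (10 against 0) and ribosomal protein genes (21 against 6), with McNemar exact adjusted p of 0.025, 0.00391, 0.0208, 0.0156 and 0.0237. Over all protein-coding genes 3883 had a BCL11A region alone and 386 a TR4 region alone, which became 1445 and 1480 with equal list lengths, a limit that itself brings such counts toward balance, and none of those 5 lists then passed (McNemar exact test, lowest adjusted p = 0.25). The direction turned for ribosomal protein genes, with 8 of BCL11A alone against 19 of TR4 alone, and for corepressors, with 3 against 5, while nuclear receptors had 1 of each, red cell membrane genes 1 against 0 and erythroid transcription factors 5 against 0.

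The calls of these groups moved with the setting. With equal list lengths the red cell membrane genes and the corepressors lost the BCL11A call (Fisher's exact test, adjusted p = 0.765 and 0.159), and the heme and iron genes the TR4 call (adjusted p = 0.0787). The red cell membrane genes also lost the BCL11A call in clone TB and with windows of 500 bases (Fisher's exact test, adjusted p = 0.0791 and 0.0742), the heme and iron genes the TR4 call with regions needed in all 3 groups of a target (adjusted p = 0.177), and the corepressors the TR4 call with windows of 5 kb (adjusted p = 0.0681).

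Markers of other cell types had few regions. Of 20 lymphoid markers, 1 had a TR4 and 0 a BCL11A region (Fisher's exact test, adjusted p = 0.0333 and 4.05e-05), of 20 myeloid markers 1 and 4 (adjusted p = 0.0333 and 0.0458), of 18 megakaryocyte markers 0 and 3 (adjusted p = 0.0135 and 0.0237), and of 20 hepatocyte markers 1 and 3 (adjusted p = 0.0333 and 0.0163). Of 20 neuronal markers, 3 and 4 had one (Fisher's exact test, adjusted p = 0.36 and 0.0458), and of 390 olfactory receptor genes 0 and 3 (adjusted p = 3.96e-53 and 1.48e-93). GP1BB, a platelet glycoprotein gene, had a peak in 9 BCL11A-directed and 0 TR4-directed libraries. Of the 10 protein-coding globin genes, 1 had a TR4 and 6 a BCL11A region (Fisher's exact test, adjusted p = 0.36 and 0.379). With windows of 5 kb the myeloid markers turned above the other genes for BCL11A without passing (55%, Fisher's exact test, adjusted p = 0.826), and lists below the other genes numbered 1 for TR4 and 3 for BCL11A. With equal list lengths only the olfactory receptors stayed below the other genes for either protein.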

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

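The tests on primary chromosomes alone, without replicate 3 of every group and of the α-globin genes under other settings were chosen after the data were seen. All overlaps stayed above independence under every alternative run, where regions of 1 library alone, which cannot be shared, lower the number expected. With the 4621 strongest peaks of each library, the share of TR4 regions that were BCL11A regions was 37.1% with MYC and 41.5% within clone TB, and the test by region called 1598 TR4-preferred and 1486 BCL11A-preferred regions. With the MYC libraries left out it called 112 and 1545 (6 against 6 libraries, so fewer samples), and with every region tested 316 TR4-preferred. Leaving out 1 library at a time, or replicate 3 of every group, gave 559 to 795 TR4-preferred regions, the highest without MYC replicate 3 of clone T, while 785 and 761 came without TR4 replicate 3 of clones T and TB; the cause was not tested. The same gave shares of 51.8% to 97.1% for HA regions that were MYC regions in clone B, 43.3% to 96.6% for TR4-antibody regions in clone T and 48.2% to 89.2% for HA regions of clone B in clone TB.

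Lists below the other genes numbered 3 for TR4 with windows of 500 bases, 1 with 5 kb, 1 with all 3 libraries needed and 1 with equal lengths. For BCL11A they numbered 3 with 5 kb, 3 in clone TB, 3 with regions of all 3 groups, 2 with all 3 libraries and 1 with equal lengths, where 5 lay above; the causes were not tested. Nuclear receptors turned above the other genes for TR4 at 34.2% (5 kb), 28.9% (clone TB), 21.1% (all 3 groups), 15.8% (all 3 libraries) and 15.8% (equal lengths), as did red cell membrane genes for TR4 at 45.8% and myeloid markers for BCL11A at 55% with 5 kb. None of these passed its test on either side except the myeloid markers in the main setting.

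Ratios of peak numbers within one target lay near 1 and turned direction. TR4 in clone TB over clone T was 0.982 with −log10 q of at least 5 and 0.84 to 1.38 with a library left out, HA over MYC in clone B 0.738 to 1.11, TR4 over MYC in clone T 0.675 to 1.11, and HA in clone TB over clone B 0.803 to 1.16. With the replicate number as a block, the test by region called 507 and 6402 regions, the gene-end share had p = 0.00025 and the Jaccard index p = 0.0002 (permutation tests), and no comparison of targets changed its side of the threshold. Comparisons of peak numbers, 3 libraries against 3, could not pass with or without the block, so they could not change. Same-numbered libraries of TR4-directed and BCL11A-directed groups correlated by 0.00459 to 0.113, all positively. The numbers were not taken to pair them, but a batch shared by replicate number was not excluded. Among single genes, regions and lists, 347 values kept their side of the threshold, 51 lost and 3 gained a call, and 7 turned direction. Depth is unknown, so its effect on the counts of regions was not tested; list length moved the counts given above. The motif comparison and its alternatives were not run.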

Other observations

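All results of this part except the tests of the MYC antibody, of list length in the test by region and of other splits were chosen after the data were seen. Gene classes outside the fixed lists were compared between the proteins, by MYC regions of clone T for TR4 and of clone B for BCL11A. Of 74 histone genes, 59 (79.7%) had a BCL11A region at a gene end and 12 (16.2%) a TR4 region, with 47 carrying BCL11A alone and 0 TR4 alone (McNemar exact p = 1.42e-14); with equal list lengths this was 4 against 0 (p = 0.125). Of 517 zinc finger genes with a ZNF symbol, 203 (39.3%) had a TR4 and 264 (51.1%) a BCL11A region, with 35 of TR4 alone against 96 of BCL11A alone (McNemar exact p = 9.4e-08), a direction that turned to 70 against 27 with equal list lengths (McNemar exact p = 1.48e-05). Of 154 snRNA genes, 42 had a TR4 and 54 a BCL11A region, with 7 of TR4 alone against 19 of BCL11A alone (McNemar exact p = 0.029), which turned to 17 against 3 at equal lengths (McNemar exact p = 0.00258). Of 429 tRNA genes, 77 (17.9%) and 172 (40.1%) had one, with 6 of TR4 alone and 101 of BCL11A alone, which became 24 and 31 at equal lengths (McNemar exact p = 0.419). Over all protein-coding genes the same limit moved 386 of TR4 alone and 3883 of BCL11A alone to 1480 and 1445. It thus moves such counts toward TR4 in general, so a turn of direction is not by itself particular to a class. Genes of such families share sequence, and how reads were assigned among copies is not given in the sources used here.

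The regions shared by the MYC antibody in clones T and B were weighed against binding of the antibody to the cells' own MYC protein. If the other antibodies gave no peaks at the sites of MYC, that would leave most of the shared regions without a region from either of them. Of the 7458 shared regions, 2.57% were in neither the TR4-antibody regions of clone T nor the HA regions of clone B, while 78.5% were in the first, 93.1% in the second and 74.2% in both. This argues against MYC at sites without such regions as the main source. MYC at sites that also hold them stays open, since no library came from cells without the tags. The shared regions not in both sets are left without that second antibody for at least one protein, and the part of the test that needs motifs was not run. The IgG libraries, 1 per clone, had 2.63% to 4.44% of peaks at gene ends and 0.997% to 3.77% of the peaks of a target library lay in IgG regions, while sharing by both proteins and signal common to the other antibodies stay open.

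The excess of BCL11A-preferred regions was to be weighed against list length by limiting every list to one length, where 1486 regions were BCL11A-preferred against 1598 TR4-preferred. Both targets then have the same number of peaks, which brings the counts toward balance whatever made the lists longer, so the test decides nothing. Depth and a larger number of sites bound by BCL11A therefore cannot be told apart here. Of 100 splits of the 18 libraries, 1 gave as many called regions, the real one with 6747, and the highest of the others gave 0. Those others mix libraries of both targets, so few or no calls were likely in any of them. The result shows that libraries group by target. It excludes no chance difference, since the libraries come from 3 clones and may be technical repeats. The 2 targets also differ in tag and, except in clone TB, in clone.

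The γ-globin peaks, in 3 of 3 HA and 3 of 3 MYC libraries of clone TB and in replicate 1 alone of each antibody in clone B, were weighed against list length differing between libraries. If list length alone decided, every library without the HBG1 peak would have a shorter list than the shortest list with it, 15163 peaks. Replicate 3 of MYC and of HA in clone B had shorter ones (13429 and 12284). However, 2 libraries without the peak had longer ones, up to 31432. List length was thus not the only source, and a part in the pattern stays open. Reads shared between the near-identical HBG1 and HBG2 copies would give both genes a peak together, and 0 libraries had a peak at one copy alone, so peaks at the 2 genes cannot be told apart from a peak at one of them. A difference between the clones, including the tagged TR4 in clone TB, stays open, since 1 clone of each kind was profiled and the HA libraries alone did not pass (Fisher's exact test, p = 0.4). The contrast of targets in gene-end share was 11.8 percentage points with MYC in the single-tag clones and 18.6 within clone TB (exact permutation test of the difference, p = 0.07, adjusted p = 0.14).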
